A study of Homo sapiens with 4 samples.

How the data were processed

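Mature miRNA counts from 4 small RNA libraries were analysed, 2 of parental A375 and 2 of vemurafenib-resistant A375-VR cells, grouped by the sample labels. Per the labels' protocols, cells were grown with 10% serum, RNA was isolated with a miRNA kit and libraries were made with a standard Illumina small RNA protocol. The labels give a maintenance dose of 1.3 µM vemurafenib, while the deposited column names of the resistant libraries say 1350 nM. Per the submitters' processing notes, CASAVA, cutadapt 1.7.1, Bowtie 1.0.0, DESeq and DESeq2 were used. The genome build, the miRNA annotation release, the mismatches allowed and the treatment of reads that fit several miRNAs are not given in the sources used here. These choices decide how reads are divided among near-identical miRNAs (miR-204-5p and miR-211-5p, miR-10a and miR-10b, the let-7 members, miR-17 with miR-20a, miR-93 and miR-106, and the copies of miR-509), so values of single members are uncertain to that extent. PCR duplicates cannot be removed, so intervals, floors and tests on summed counts cover counting error only.

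The deposited counts are whole numbers per mature miRNA, not normalized, in a table of the whole series and again in a file per sample, and all 2588 values of each sample file equal the table. The deposited normalized signal values are the counts divided by 1 size factor per library (0.462, 1.27, 1.21 and 1.54), which the authors computed with DESeq or DESeq2, both named in the notes. Multiplied back, 100% of these values were whole within 1e-06 and equal to the counts, so a count test on them is the main test itself and calls the same 53 miRNAs.

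Within groups, replicates differed by more than sampling noise. A chi-square over miRNAs with a summed count of 20 or more gave 6.19 per degree of freedom in the parental pair (237 miRNAs) and 4.40 in the resistant pair (273 miRNAs), so neither pair is 1 library deposited again. The between-group pairs gave 18.7 to 31.0.

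The test was edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr at a minimum count of 10, a quasi-likelihood F-test on group and Benjamini-Hochberg adjustment over the tested miRNAs at 0.05. The filter kept 276 miRNAs with 99.8% of the counts. The common dispersion was 0.00218, a biological coefficient of variation of 4.67%, with 2 residual and 17.5 prior degrees of freedom. The median standard error of a log2 fold change was 0.17. CPM values are counts scaled by TMM-adjusted library totals, given as mean ± SD over 2 libraries. Ratios of low counts are scaled by effective library size, with exact conditional 95% intervals, and a count of 0 is given a floor of 3 counts of the library total. 16 miRNA lists were fixed before the data were examined, and the 11 lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with camera with estimated correlation and fry as checks. With an estimated correlation, camera uses the residual degrees of freedom, here 2, so that check has little power. Arm usage was tested with diffSpliceDGE on precursors with both arms tested. Positions are those of GENCODE release 29 on GRCh38, matched by miRNA name, where 2381 of the 2588 names matched 1 gene, 178 more than 1 and 29 none.

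Named miRNAs follow a rule fixed before the data were examined. They are the tested members of the miR-204/211 family, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM and groups that do not overlap, the 5 most abundant, the 2 most abundant tested members of each list, and 3 precursors by arm usage if past the threshold, which none was. Unchanged members of the lists may be left out, and 10 were. Further changed list members, and the members called when adjusted over the list alone, were chosen after their values were seen.

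The steps were tested on simulated counts with the means and library sizes of these libraries, for resistant against parental. With 200 changed miRNAs, edgeR recovered 12 of 19 tested ones changed 1.5-fold, 26 of 33 changed 2-fold and 28 of 28 changed 4-fold. It called 2 of 207 unchanged ones, with 287 tested. With nothing changed it called 0 of 277. diffSpliceDGE called 10 of 10 precursors with 1 arm changed 4-fold and 0 of 48 others, and camera called the 1 list shifted 1.5-fold and 0 of 10 others. In each of these runs no other miRNA was changed. Smaller arm changes and list shifts were not simulated. Counts were drawn independently for each miRNA at the common dispersion. The simulated false calls therefore do not cover correlated miRNAs, on which the list tests depend, or miRNAs with spreads of their own.

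The alternatives were other scalings (RLE, library totals, upper quartile), no filter or a mean of 10 CPM, DESeq2 1.42.0, limma on log2 of the deposited normalized values with a pseudocount of 1, limma-voom, a replicate block, robust dispersion, leaving out each library, a log2 fold change of at least 1, and shares without the most abundant miRNA. Thinning all libraries to the shallowest and DESeq2 without independent filtering were added after the data were seen.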

Results

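Small RNA libraries were sequenced from A375, a human melanoma cell line with an activating BRAF mutation, and from A375-VR, a population derived from it that grows in vemurafenib, an inhibitor of mutant BRAF. The labels give 2 libraries of untreated parental cells and 2 of resistant cells, which were selected with increasing vemurafenib from 10 nM and then kept uncloned in 1.3 µM. Counts were deposited for 2588 mature miRNAs, of which 846 had a count in at least 1 library. The total counts were 235732 and 635503 in parental replicates 1 and 2, and 599355 and 773660 in resistant replicates 1 and 2. The deepest library thus held 3.28 times the counts of the shallowest. The libraries listed 495, 639, 609 and 667 miRNAs with a count, in the same order. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The resistant cells were kept in the drug and the parental cells were not, so the comparison covers resistance and drug exposure together.

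The comparison asked which miRNAs differ between vemurafenib-resistant and parental cells, with miR-204-5p and miR-211-5p named by the title of the study. Both were higher in the resistant cells. miR-211-5p, which melanocytes express from an intron of TRPM1, went from 0 and 1 counts in the parental libraries to 35 and 52 in the resistant libraries. miR-204-5p, a close relative in sequence, rose 1.78-fold from an already high level. Members of an X-linked miRNA cluster also rose, and the largest falls were those of miR-381-3p, miR-4454 and miR-409-3p. Of 276 miRNAs tested, 53 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 23 of them higher and 30 lower in resistant cells, and 85 had an unadjusted p under 0.05. Most changes were small, with a median absolute log2 fold change of 0.49 among the 53, and 10 reached 2-fold, 4 higher and 6 lower. In all 53 the resistant libraries lay on one side of the parental libraries, as in 167 of the 276 tested, or 60.5%, where chance gives 33.3%. The split of higher and lower depended on the scaling. It was 44 and 21 with library totals and 9 and 36 with the upper quartile, which moved the median log2 fold change of the tested miRNAs to 0.119 and -0.138, from 0.02. Limma on the deposited normalized values, which changes the test together with the scaling, gave 36 and 23, with a median of 0.103. The number of changed miRNAs was 21 without parental replicate 1, 1 without parental replicate 2, 27 without resistant replicate 1 and 22 without resistant replicate 2, and DESeq2 gave 24. Without parental replicate 2, the parental group is the shallowest library alone, and the only call was miR-204-5p.

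**Figure D1:**
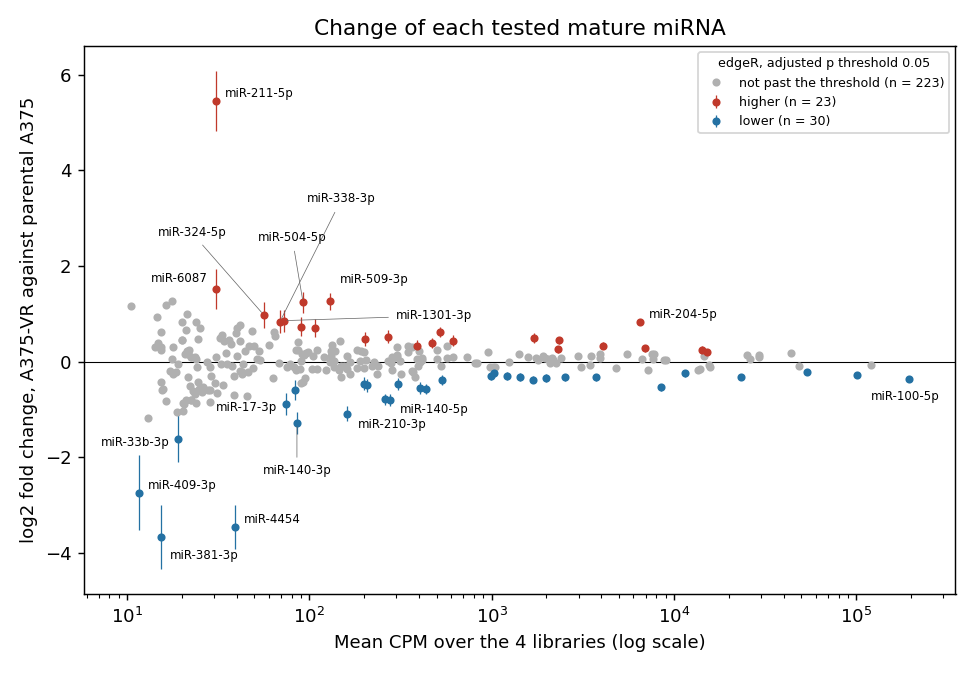
Log2 fold change of A375-VR against parental A375 on the vertical axis, against mean CPM over the 4 libraries on a log scale, for the 276 tested miRNAs. Red points are the 23 higher and blue points the 30 lower miRNAs at an adjusted p of 0.05, with bars of 1 standard error, and grey points are the 223 others; miR-211-5p stands highest at 5.45 and miR-381-3p lowest at -3.68.

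miR-204-5p had 4707 ± 2.55 CPM in parental and 8378 ± 120.3 CPM in resistant cells (SD, n = 2 each). Its log2 fold change was 0.83 with a standard error of 0.06 (edgeR, adjusted p = 1.28e-08), and both resistant libraries exceeded both parental libraries. Its precursor lies on chromosome 9 from 70809975 to 70810084 on the minus strand, in an intron of TRPM3 (GENCODE release 29, GRCh38). miR-211-5p had 0.805 ± 1.14 CPM in parental and 60.7 ± 6.49 CPM in resistant cells (SD, n = 2 each). The 0 in parental replicate 1 allows up to 12.7 CPM of the library total. The summed counts of 1 and 87 gave a ratio of 51.8 after scaling, with an exact 95% interval from 9.05 to 2067 that covers counting error only. The fitted log2 fold change was 5.45 with a standard error of 0.63 (edgeR, adjusted p = 5.72e-06). Without parental replicate 2 the parental count is 0, the fitted log2 fold change was 8.08, which then depends on the prior count, and the adjusted p was 0.0917. Over all its alternatives the adjusted p ran from 8.06e-15 to that value. The precursor of miR-211 lies on chromosome 15 from 31065032 to 31065141 on the minus strand, in an intron of TRPM1. The mature sequences of miR-204-5p and miR-211-5p are nearly identical, and the way the counting divided reads that fit both is not given in the sources used here. The other arm, miR-204-3p, had 6 counts in parental and 9 in resistant cells and was not tested. Since the study picked this pair, its 2 of 2 members higher, over all miRNAs and adjusted over the list alone, is not independent evidence.

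Among the other large rises, miR-6087 went from 16.2 ± 2.41 to 45.6 ± 14.8 CPM (SD, n = 2 each), with a log2 fold change of 1.52 and a standard error of 0.41. miR-504-5p, from an intron of FGF13 on the X chromosome (138667711 to 138667793, minus strand), rose by 1.24 ± 0.22 (log2, SE), from 57.7 ± 13.3 to 127.1 ± 12.9 CPM. miR-324-5p rose by 0.97 ± 0.27, miR-1301-3p, in an intron of DNMT3A, by 0.86 ± 0.23, and miR-338-3p, in an intron of AATK, by 0.84 ± 0.23 (log2, SE). Their adjusted p values in edgeR were 0.0111 for miR-6087, 0.000327 for miR-504-5p, 0.0131 for miR-324-5p, 0.0111 for miR-1301-3p and 0.0125 for miR-338-3p. With a library left out, miR-504-5p missed the threshold only without parental replicate 2, miR-6087 passed it only without resistant replicate 2 and miR-1301-3p only without resistant replicate 1. miR-324-5p, at 1.83 without parental replicate 2, and miR-338-3p missed it whichever library was left out.

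Among the falls, miR-4454 went from 72.1 ± 24.5 to 5.89 ± 3.004 CPM (SD, n = 2 each), a log2 fold change of -3.46 with a standard error of 0.46 (edgeR, adjusted p = 2.2e-05). miR-210-3p, the miRNA best known for its induction by hypoxia, fell from 217 ± 34.8 to 107 ± 0.481 CPM, a log2 fold change of -1.09 with a standard error of 0.15 (edgeR, adjusted p = 3.84e-05). It lies on chromosome 11 from 568089 to 568198 on the minus strand, in an intron of MIR210HG. Both arms of miR-140, which lies in an intron of WWP2, were lower, miR-140-3p by a log2 fold change of -1.28 and miR-140-5p by -0.80, the latter from 350.5 ± 3.97 to 200.4 ± 4.57 CPM. Without parental replicate 2, miR-140-3p was at -0.72 (edgeR, adjusted p = 0.246, the highest of its alternatives, from 4.85e-08). miR-33b-3p, from an intron of the lipid regulator SREBF1, changed by -1.61 ± 0.50 (log2, SE; edgeR, adjusted p = 0.0236), and miR-17-3p by -0.89 ± 0.23 (adjusted p = 0.0102), and both missed the threshold whichever library was left out. Without parental replicate 2, which leaves the shallowest parental library alone, 50 of the 53 changed miRNAs missed the threshold and a further 2, miR-381-3p and miR-409-3p, were not tested.

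**Figure D2:**
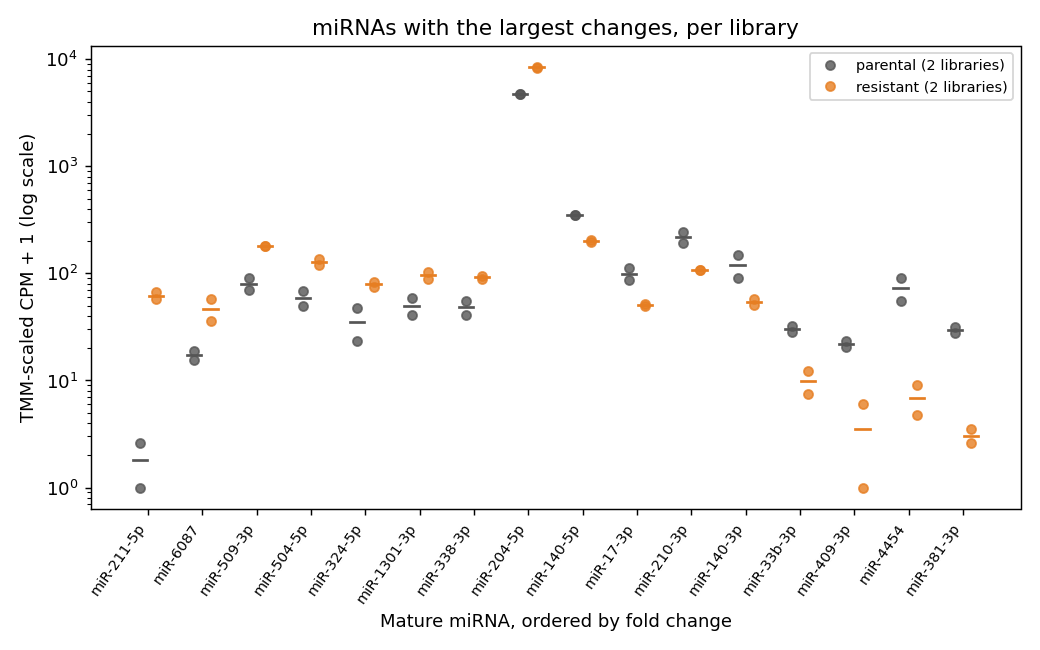
Normalized abundance, as TMM-scaled CPM plus 1 on a log scale, of the 8 miRNAs with the largest rises and the 8 with the largest falls, with 1 point per library (2 parental in grey, 2 resistant in orange) and a dash at each group's mean. miR-211-5p goes from 0 and 1 counts to 35 and 52. In each of the 16 miRNAs both resistant libraries lie on one side of both parental libraries, because the rule that picked them required it.

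The X-linked cluster at Xq27.3, a primate-expanded group of miRNAs expressed in testis and in melanocytes, had 2 of 7 tested members higher, 0 lower and 5 not past the threshold. The members that rose were miR-509-3p, from 79.3 ± 14.3 to 179 ± 0.883 CPM (SD, n = 2 each; log2 fold change 1.26, SE 0.17, edgeR, adjusted p = 3.77e-05), and miR-508-3p, from 410.2 ± 29.9 to 637 ± 39.8 CPM (log2 fold change 0.61, SE 0.10, adjusted p = 0.000284). miR-508 lies on the X chromosome from 147236913 to 147237027 on the minus strand, and miR-509-3p can come from 3 annotated loci whose reads cannot be told apart. The median log2 fold change of the 7 was 0.61. Camera with a preset correlation of 0.01 gave an adjusted p = 0.00512 for a rise against the other miRNAs. With an estimated correlation, which was -0.096 and so not above the preset, camera gave an adjusted p = 0.618. In limma, fry, which asks whether the members moved one way on balance, gave an unadjusted p = 0.00392, a value from a model across all miRNAs. Fry also gave an unadjusted p under 0.05 for let-7 (0.0267), miR-30 (0.0366) and ERK (0.0427), whose camera tests did not pass. These fry values are not adjusted over the 11 lists.

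Both tested members of the imprinted 14q32 cluster, a large group of miRNAs between DLK1 and DIO3, fell. miR-381-3p had 6 and 19 counts in the parental and 1 and 2 in the resistant libraries, a scaled ratio of 0.0714 with an exact 95% interval from 0.0138 to 0.234. Its fitted log2 fold change was -3.68 with a standard error of 0.67 (edgeR, adjusted p = 0.000496). miR-409-3p had 5 and 12 counts against 0 and 4, a scaled ratio of 0.140 with an interval from 0.0343 to 0.429, and a log2 fold change of -2.74 with a standard error of 0.79 (edgeR, adjusted p = 0.0151). The 0 in resistant replicate 1 allows up to 5.01 CPM of the library total. The call of miR-409-3p was lost without parental replicate 1 (adjusted p = 0.16) and without resistant replicate 1 (0.144; log2 fold change -1.93), and its log2 fold change was -6.32 without resistant replicate 2 (0.0491). Its adjusted p ran from 0.00146 to 0.16 over its alternatives, and without parental replicate 2 neither member was tested. The list of mesenchymal and stromal miRNAs had a median log2 fold change of -0.27 in the same comparison. The precursors lie on chromosome 14 on the plus strand, miR-381 from 101045920 to 101045994 and miR-409 from 101065300 to 101065378. The C19MC cluster, a placental group on chromosome 19, had 0 members tested, with 23 counts in parental and 36 in resistant cells, a scaled ratio of 0.931 with an interval from 0.537 to 1.65.

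In the growth-associated miR-17/92 and paralogous clusters, 0 of 15 members were higher, 3 lower and 12 not past the threshold. The 3 lower members, miR-17-5p, miR-17-3p and miR-20a-5p, lie in exons of MIR17HG. The tested miR-18a-5p, miR-18a-3p and miR-19a-3p lie in the same transcript and did not pass, and miR-20a-5p fell from 1908 ± 17.1 to 1466 ± 10.9 CPM (SD, n = 2 each). In the let-7 family, whose members repress growth and developmental timing genes, 1 of 14 was higher and 2 were lower. let-7c-5p had a log2 fold change of 0.52, let-7a-5p of -0.21 and let-7b-5p of -0.34, and these differ by few bases. In the family of miR-99, miR-100 and miR-125 0 of 9 were higher and 3 lower, namely both arms of miR-100 and miR-125b-1-3p. miR-100-5p, the most abundant miRNA, had a log2 fold change of -0.36 with a standard error of 0.07 (edgeR, adjusted p = 0.000496). Camera gave adjusted p values of 0.252 for miR-17/92, 0.252 for let-7 and 0.57 for the miR-99, miR-100 and miR-125 family, so none of these lists as a whole passed the test against the other miRNAs. Leaving out 1 library put miR-17-5p between -0.33 and -0.24 and miR-100-3p between -0.37 and -0.22 (log2), and neither call held in every case. With a library left out, miR-20a-5p was lost only without parental replicate 2, let-7b-5p passed only without either library numbered 1 and was at -0.22 without parental replicate 2, let-7c-5p only without resistant replicate 2, miR-100-5p only without resistant replicate 1, with -0.24 without parental replicate 1, and miR-17-3p, let-7a-5p and miR-125b-1-3p passed in no case.

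Of miRNAs that respond to ERK signalling, the pathway downstream of BRAF, 0 of 7 were higher and 2 lower, both arms of miR-21. miR-21-3p went from 10111 ± 329 to 6961 ± 326 CPM (SD, n = 2 each; log2 fold change -0.54, SE 0.06, edgeR, adjusted p = 6.48e-06) and miR-21-5p had a log2 fold change of -0.31. Adjusted over the list alone, 2 were higher, miR-221-3p and miR-132-3p, and 2 lower. In the inflammatory list, miR-146a-5p, a feedback inhibitor of NF-kB signalling, was higher with a log2 fold change of 0.49, and miR-155-5p, which is processed from MIR155HG, was lower at -0.79 (edgeR, adjusted p = 0.00111 and 0.000112), with 2 of 4 not past the threshold. In the p53-induced list 1 of 5 was higher, miR-192-5p at 0.25. In the miR-30 family 1 of 11 was higher, miR-30b-5p at 0.28. The cluster of miR-183, miR-96 and miR-182, with 3 tested, and the miR-29 family, with 5, had 0 changed members at an adjusted p of 0.05 in edgeR, with 0 and 1 at an unadjusted p under 0.05, and 0 in DESeq2, limma and limma-voom. With a library left out, miR-21-3p and miR-155-5p were lost only without parental replicate 2, miR-146a-5p passed only without resistant replicate 1 and was at 0.30 without resistant replicate 2, miR-21-5p and miR-30b-5p passed only without resistant replicate 2, and miR-192-5p passed in no case. Camera gave adjusted p = 0.976 for the inflammatory list and 0.57 for the ERK, p53, miR-30, miR-183 cluster and miR-29 lists. The median, mean and test differed in sign for 3 lists. For p53 the median was 0.25, the mean -0.02 and the test up. For the inflammatory list the median was 0.23, the mean 0.09 and the test down. For miR-29 the median was 0.03, the mean -0.15 and the test down.

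Of mesenchymal and stromal miRNAs, 0 of 8 were higher, 3 lower and 5 not past the threshold. The 3 were miR-10a-5p, a HOXB-cluster miRNA that fell from 110223 ± 1300 to 91160 ± 2950 CPM (SD, n = 2 each), miR-199a-3p and miR-199b-5p. miR-199a-3p, at -0.47, has the same mature sequence as miR-199b-3p, which was listed separately at -0.27 and did not pass (edgeR, adjusted p = 0.157), so its call depends on how identical reads were divided. The other arm, miR-199a-5p, was at -0.26 (adjusted p = 0.285). With a library left out, miR-10a-5p passed only without resistant replicate 2, miR-199a-3p only without resistant replicate 1 and miR-199b-5p, at -0.26 without parental replicate 1, in no case. The median log2 fold change was -0.27, and camera gave an adjusted p = 0.0486, with adjusted p = 0.618 with an estimated correlation and a fry p of 0.0757. That call was lost under 7 of 12 alternatives, where the adjusted p ran from 0.0389 to 0.236 over the 12. Of the markers of other cell types, the epithelial list had 1 tested member, miR-200c-3p, at -0.68 (adjusted p = 0.333). The blood-cell, endothelial, liver and muscle list had 2, miR-126-5p at 0.22 and miR-126-3p at 0.21 (edgeR, adjusted p = 0.423 and 0.767), and its summed counts of 137 and 268 gave a scaled ratio of 1.16 with an exact 95% interval from 0.944 to 1.44. Apart from the list of miR-99, miR-100 and miR-125, with 4 lower including miR-125b-5p, and the ERK list, the counts adjusted over the list alone equalled those over all miRNAs.

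**Figure D3:**
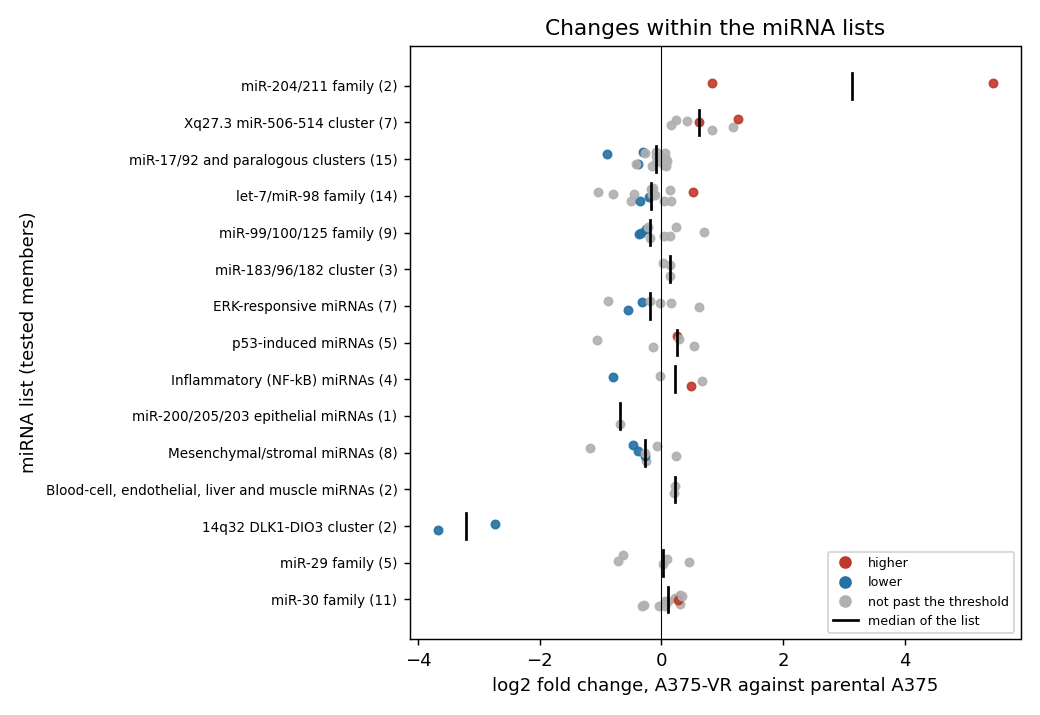
Log2 fold change of A375-VR against parental A375 for each tested member of the miRNA lists fixed in advance, with the number of tested members in brackets and a black line at each list's median. Red points are higher, blue points lower and grey points not past an adjusted p of 0.05; both 14q32 members lie at the low end, at -3.68 and -2.74, and the Xq27.3 members have a median of 0.61.

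Of 64 precursors with both arms tested, 0 of 128 arms passed the threshold in edgeR's diffSpliceDGE, with 9 at an unadjusted p under 0.05 and a smallest adjusted p of 0.113, and no other tool was run for it. A dominant arm lies close to the fit of its precursor, as did miR-100-5p (98.7% 5p in parental cells, diffSpliceDGE, unadjusted p = 0.996). Such arms could hardly pass, yet they count in the adjustment. The arms of miR-30a moved apart, 5p at -0.32 and 3p at 0.30, without passing (diffSpliceDGE, adjusted p = 0.528 for each). Simulated arm changes were 4-fold, so the power for smaller shifts between arms is not known. Both arms passed the test of abundance in 6 precursors, and in all 6 both arms were lower, namely miR-100, miR-1307, miR-140, miR-17, miR-193a and miR-21.

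The libraries were dominated by a few miRNAs. The 5 most abundant, miR-100-5p, miR-10b-5p, miR-10a-5p, let-7a-5p and miR-92a-3p, held 54.0% ± 1.09 of the counts in parental and 49.2% ± 0.436 in resistant cells (SD, n = 2 each). miR-100-5p alone held 21.03% ± 1.44 and 17.62% ± 0.817. miR-204 and miR-211 together rose from 0.454% ± 0.0103 to 0.874% ± 0.00591 of all counts. These shares are given without a test, as planned, and the smallest two-sided exact permutation p for 2 against 2 libraries is 0.333. miR-10b-5p and miR-92a-3p were not past the threshold, with log2 fold changes of -0.08 and -0.09 that turned positive with library totals, at 0.03 and 0.01.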

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

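Thinning to the shallowest library and DESeq2 without independent filtering were chosen after the data were seen. No changed miRNA had the opposite sign under any of the 16 alternatives in which it was tested. miR-204-5p passed the adjusted p threshold in all 16, with log2 fold changes from 0.69 to 0.93, so a minimum of 1 leaves it out. The count of 53 changed miRNAs (23 higher, 30 lower) became 24 (14, 10) with DESeq2, which gave an adjusted p to 76 miRNAs, 27 (9, 18) with DESeq2 without independent filtering and 10 (4, 6) with a log2 fold change of at least 1, which by construction keeps fewer. Library totals gave 44 higher and upper quartile 9, as these scalings shift all fold changes. Limma on the deposited normalized values gave 36 higher, and the cause was not tested. Leaving out 1 library gave 1 to 27 changed, 1 to 11 higher and 0 to 16 lower, with fewer samples to estimate the spread. The lowest came without parental replicate 2, which leaves only the shallowest parental library. A lone library takes its spread from the other group. Thinned libraries gave 44 changed of 192 tested, so depth limits how many can be tested.

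Of 2 lists called, 1 was called with the upper quartile, with a mean of 10 CPM and with the replicate block, and 1 to 3 when a library was left out. The Xq27.3 cluster was called in all 12 alternatives that test lists and the mesenchymal list in 5, all with the preset correlation. With an estimated correlation neither passed (adjusted p = 0.618 for both). Of lists with too few members for a main test, 14q32 passed as lower without a filter and without resistant replicate 1 or 2 (adjusted p = 1.15e-06, 0.000899 and 8.02e-05) and the miR-204 and miR-211 family as higher without a filter (adjusted p = 0.0108), and none with an estimated correlation (adjusted p = 0.502 to 0.882). Why these small lists passed in some alternatives was not tested. Replicate numbers are shared numbers only (correlation of same-numbered deviations 0.04 across 276 miRNAs), and the replicate block gave 60 changed, 52 of them shared. The share of the 5 most abundant miRNAs became 46.7% and 44.2% without the most abundant one, and that of miR-204 and miR-211 0.575% and 1.06%, through the smaller denominator. The sample files equal the table and gave no alternative.

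Some results that passed no threshold turned direction, and the cause was not tested. The list test of the inflammatory list turned with medians of 0.0886 (upper quartile), 0.67 (no filter), 0.25 (mean of 10 CPM), 0.24 (replicate block), 0.257 (without parental replicate 1) and 0.343 (without resistant replicate 1), that of miR-99, miR-100 and miR-125 at -0.0137 (without parental replicate 2) and that of miR-29 at -0.00119 (without parental replicate 1). With a library left out, the medians ran from 0.0417 to 0.343, from -0.230 to -0.0137 and from -0.321 to 0.0429. The medians themselves changed sign in 5 of 12 alternatives for miR-29, 2 for miR-17/92 (highest 0.00533) and 1 each for the inflammatory list (lowest -0.0515), the miR-183 cluster (-0.0192) and miR-30 (-0.0458). Of single miRNAs, miR-152-3p was at -0.068 with the upper quartile. miR-10b-5p was at 0.026 with library totals and 0.010 with limma on the deposited values. miR-92a-3p was at 0.011 with library totals and between -0.214 and 0.0839 with a library left out. With a library left out, miR-126-3p ran from -0.0405 to 1.46, at -0.0372 without parental replicate 1, and miR-126-5p from -0.0392 to 0.421. The choice to print no values for 10 unchanged list miRNAs was made after they were seen. Of these, 7 changed sign in at least 1 alternative, in 18 of 157 values, and 0 of the 18 passed the threshold. The 9 that passed, with the sign of the main test, were of let-7f-5p (4), miR-99b-5p (4) and miR-194-5p (1).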

Other observations

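All tests below were chosen after the related results had been seen, except the comparison of neighbours with freely shuffled pairs and that of chromosomes, whose outcomes were stated first. Outside the lists, and chosen after their values were seen, further miRNAs differed between the lines. Both arms of miR-193a were lower, with log2 fold changes of -0.47 and -0.54, as were both arms of miR-1307, at -0.57 and -0.50. miR-148a-3p, miR-148b-3p and miR-152-5p were higher by 0.24, 0.43 and 0.69 (edgeR, adjusted p = 0.0245, 0.0111 and 0.0111). miR-152-3p, which shares the seed of miR-148a-3p and miR-148b-3p, did not pass, at 0.10 (adjusted p = 0.868), nor did miR-148a-5p, at -0.22 (adjusted p = 0.183). miR-138-5p rose from 1995 ± 126 to 2697 ± 187 CPM (SD, n = 2 each; log2 fold change 0.45, adjusted p = 0.000327). miR-151a-3p, in an intron of PTK2, was higher by 0.34 and miR-378a-3p, in an intron of PPARGC1B, by 0.20 (edgeR, adjusted p = 0.0012 and 0.0212). The calls in this paragraph are lost without parental replicate 2, where miR-148a-3p is at 0.13 and miR-148b-3p at 0.16, miR-193a-3p is at -0.35 without resistant replicate 2, and of the changed miRNAs named here only miR-138-5p and miR-1307-5p hold without each other library.

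The rise of miR-211-5p was set against reads of its near copy and against depth. If misassigned miR-204-5p reads were the source, the ratio of both would be equal in the lines, but miR-211-5p had 0 and 0.342 counts per 1000 of miR-204-5p in the parental and 6.77 and 7.72 in the resistant libraries (Fisher's exact test, two-sided p = 4.84e-10 on summed counts). Lower depth is argued against by parental replicate 2, deeper than resistant replicate 1 and with 1 count against 35 (exact binomial p = 2.37e-10, which compares those 2 libraries). Both p-values treat reads as independent molecules and cover counting error only. Whether part of the miR-204-5p rise comes from miR-211-5p reads cannot be told apart, since the other arm, miR-204-3p, had too few counts (ratio 0.8923, 95% interval 0.284 to 3.05). Drug exposure and resistance are confounded by the design, and no biological explanation was tested.

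The fall of miR-381-3p and miR-409-3p may reflect lower expression of the whole 14q32 cluster. The other 17 list members with a count, a set defined by not being tested, summed to 63 counts in parental and 17 in resistant cells, a scaled ratio of 0.1605 (exact 95% interval 0.0881 to 0.278), with more counts in parental for 14, in resistant for 2 and equal counts for 1, although the resistant libraries together are deeper. The libraries held 15 and 48 against 9 and 8 of these counts. Stromal cells mixed into the parental cultures cannot be told apart from this, because miR-143 and miR-145 had 12 and 18 counts, all of miR-143-3p (ratio 0.8923, interval 0.407 to 2.03). The mesenchymal and stromal list moved the same way but far less, with a median log2 fold change of -0.27 (camera, adjusted p = 0.0486, or adjusted p = 0.618 with an estimated correlation). The tested 14q32 members were at -3.68 and -2.74. Of the list, miR-199a-3p was at -0.47, miR-199b-5p at -0.39 and miR-214-3p at -1.17, the last not past the threshold (edgeR, adjusted p = 0.222). The very abundant miR-10b-5p, at -0.08, and miR-199b-3p, at -0.27, did not pass either. miR-10a-3p went the other way, at 0.25, without passing. miR-214-3p had only 4 and 11 counts in the parental and 8 and 3 in the resistant libraries, and it ran from -2.15 to -0.47 over its alternatives. What would lower the cluster was not tested.

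Neighbouring miRNAs within 10 kb on one strand differed less in log2 fold change than other pairs, which may reflect shared primary transcripts. Over 25 pairs the mean absolute difference was 0.219, against 0.648 for shuffled pairs (one-sided permutation p = 7e-05, 100000 shuffles). However, in 0 pairs did both members pass the threshold and in 5 did 1 pass, and only 17 of the 25 pairs had the same sign. Much of the gap goes with the small changes of the 41 paired miRNAs, since shuffling among these alone gave 0.286 (one-sided permutation p = 0.019), so small changes are argued against only as the whole cause. Shuffling within 4 bins of abundance gave 0.408 and a one-sided permutation p = 0.0028, so part of the gap goes with abundance. That shuffle mixed the paired miRNAs with the others, whose changes were larger (median absolute log2 fold change 0.298, against 0.141). It therefore cannot separate lower noise of abundant neighbours from the small changes of the paired miRNAs.

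Higher dosage of the whole X chromosome could raise miR-504-5p and the Xq27.3 cluster together. The other 25 tested X-linked miRNAs had a median log2 fold change of 0.06882 (bootstrap interval -0.047 to 0.204). That lies below a bound of 0.3, chosen after the related results were seen. Of the 25, 1 passed the threshold, miR-6087 at 1.52. The bootstrap treats these miRNAs as independent, although some are arms of the same precursor, such as those of miR-221. The interval is therefore likely too narrow to decide against higher dosage. Copy number changes of whole chromosomes remain open, as 0 of 18 chromosomes passed in camera (smallest adjusted p = 0.114, for X, with 1 at an unadjusted p under 0.05), and a missed threshold excludes nothing, although the outcome stated first had counted it against the explanation. The 30 miRNAs of the X set include miR-504-5p and the Xq27.3 members with 1 locus. The value for X thus rests in part on the rises to be explained. With an estimated correlation camera gave X an adjusted p = 0.857. A gain of part of the X chromosome was not tested.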
